A study of Mus musculus with 4 samples.

How the data were processed

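The study measured RNA in single nuclei from kidney cortex with outer medulla of 4 samples, 2 untreated (CT9w) and 2 given cisplatin (Cis9w). Nuclei were released by homogenisation, passed through strainers and loaded on a droplet system with a 3' kit, per the labels' protocols. Cell Ranger 5.0.1 and the mouse build mm10 are named in the submitters' processing notes. The clustering, the filters on nuclei, the treatment of doublets and free RNA, the test behind the p-values and any adjustment of them are not given in the sources used here. The cohort's unit is the sample, but both tables hold values that the authors pooled over nuclei. Whether 1 or 2 libraries per group entered the proximal tubule table is not given in the sources used here. The descriptions of the replicate-1 samples name it, and its UMIs are 57.6% of those in the 6 proximal tubule clusters.

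Each table lists per gene an average, a log2 fold change and a p-value, per the file headers. The averages are a signal, normalised UMIs per nucleus, that the authors scaled so that each column sums to one total, 2797 in the proximal tubule table and 2008 in the cluster table. The deposited log2 fold change compares Cis9w with CT9w in one table and each cluster with all other nuclei in the other. The deposited p-value equals 1 for 82.4% of proximal tubule genes. The proximal tubule table holds 21312 genes, of which 21288 IDs matched GENCODE M21 (GRCm38, the same assembly as mm10), and the cluster table holds 24468, of which 24432 matched. Gene symbols are those the authors paired with the IDs, and where 1 symbol stood for more than 1 ID (14 symbols in the proximal tubule table) the first was used. One cluster has the name PT-injury/repair in the upper header line and a number in the lower one, and the name was used.

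UMI sums were recovered from the averages. In each column nearly all values are whole multiples of 1 step, within 0.1 UMI for at least 99.995% of genes, and the inverse of the step is the sum of the nuclei's size factors, 1832 for CT9w and 3060 for Cis9w. Adding 1 to the UMI sums and to the size factor sums gives the deposited log2 fold changes of the proximal tubule table within 0.0162. From these sums, ratios of averages were given 95% Clopper-Pearson intervals, and a ratio against 0 UMIs was set against 3 UMIs over the group. The intervals cover counting error only. The 2 tables were scaled separately, so levels were not compared across them.

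A gene counted as called when the deposited p was under 0.05, with the sign of the deposited log2 fold change as its direction. The expression floor was the median over genes of the mean of both averages, 0.0154 normalised UMIs per nucleus, and 10656 genes reached it. No test across samples was run, since no column is labelled with a sample and each group has 1 column. The count adjusted over the list alone was not computed, since whether the deposited p-values are adjusted is not given in the sources used here. For 24 pathway and quality lists and 23 cell type marker lists, the median deposited log2 fold change of members at the floor was placed among 10000 random lists of the same size, drawn within 10 bins of mean level, as a description of these pools. Lists with fewer than 3 members at the floor have values only. No member at the floor had 0 UMIs in a group in any list, so no list median rests on a bound. In each cluster a marker passed at a log2 fold change of at least 1 and a p under 0.05.

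The genes named were fixed by rule. They are the 12 largest rises and 12 largest falls among called genes at the floor, up to 3 called rises and 3 called falls per list, 5 injury genes and 5 proximal tubule genes named whatever their value, and the 5 leading genes of each cluster, of which some are named. One gene among the largest rises is not reported here. The 47 lists, the named-gene rule, the comparisons of the report and the other settings named next were written before the data were examined. The other settings were a p under 0.01, a log2 fold change of at least 1, other floors, subtraction of the median log2 fold change (0.03), fold changes recomputed from the averages with a pseudocount at the 10th percentile (0.000546), means in place of medians, Spearman in place of Pearson, and other marker scores.

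For the closing section, the UMIs of nuclei outside the 17 listed clusters were solved from the deposited log2 fold changes, which compare each cluster with all other nuclei, listed or not. The averages of each proximal tubule pool were fitted as a mix of the 17 cluster profiles and that remaining profile by non-negative least squares with Poisson weights, with 200 resamplings of genes. Intervals of medians and of r given there were also drawn by resampling genes, which are not independent. These fits, the list of sex-biased genes, and the random splits of each gene's UMIs between the pools by size factor were added after the data were seen.

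The recovery of UMIs, the mix, the placement of lists and the counting intervals were tested on simulated data, and the marker scores and correlations were not. Simulated UMI sums were recovered exactly for 100% of 21312 genes in the CT9w proximal tubule averages, and UMIs of a simulated group outside the clusters for 100% of 24468 genes. Simulated mix shares were off by at most 0.862 percentage points in 20 pools. These pools were Poisson draws from the listed profiles themselves, without the remaining profile. The error leaves out misfit of the profiles to the real pools, where other weights moved some shares by more. Of random 30-gene lists, 4.5% fell outside the middle 95%, and 100% of lists raised by 0.5 on the log2 scale were found above it, each over 10656 genes of the Cis9w against CT9w comparison. A simulated ratio of 3 lay inside its counting interval in 97% of 1000 draws. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.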

Results

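Kidney nuclei were profiled from male C57BL/6 mice that had received repeated low-dose cisplatin, a platinum chemotherapy drug that injures the proximal tubule, and from untreated mice. The treated group, Cis9w, had 4 weekly injections of 8 mg/kg, and kidneys were taken 9 weeks after the first injection. The untreated group is CT9w. Each group had 2 samples, labelled by replicate number, for 4 in all. RNA of single nuclei from cortex with outer medulla was counted as unique molecular identifiers (UMIs) in a droplet 3' assay. The values used here are 2 tables that pool nuclei, and no column is labelled with a sample, so no spread between replicates could be computed. The descriptions of the replicate-1 samples name the proximal tubule table and those of the replicate-2 samples the cluster table. The proximal tubule table holds 57.6% as many UMIs as the 6 proximal tubule clusters of the other table. If 1 sample per group entered it, its comparison is between single animals. The proximal tubule pool of CT9w held 5123727 UMIs and that of Cis9w 8557662 UMIs, 1.67 times as many. An average based on 3 UMIs is 0.00164 normalised UMIs per nucleus in CT9w and 0.000981 in Cis9w. The 17 clusters of the other table held 36068714 UMIs, from 254460 in mixed-2 to 7425098 in PT-S2/S3. Intervals of ratios below are 95% intervals for 2 UMI sums (Clopper-Pearson) and cover counting error only. They leave out the differences between nuclei and between animals.

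The cluster table describes which kidney cell types were caught. The authors named 6 clusters for proximal tubule segments or states, and these held 65.9% of the UMIs in the listed clusters. Of the 15 clusters named for a cell type, 14 had a marker list of their own name as the highest scoring one, among lists with at least 3 markers past the threshold. In PT-S1 all 8 markers of the first proximal tubule segment passed, with a mean log2 fold change against all other nuclei of 2.65 in the authors' deposited table. The sodium-glucose cotransporter gene Slc5a2 averaged 1.09 normalised UMIs per nucleus in PT-S1 and 0.0181 in PT-S3-2. Markers of the third segment passed for 9 of 10 genes in PT-S3-2 and for 5 of 10 in PT-S3-1. The cystine and aspartate transporter gene Slc7a13 averaged 5.08 normalised UMIs per nucleus in PT-S3-2, 4.80 in PT-S3-1 and 2.21 in PT-S2/S3. PT-S2 was the exception, as its second-segment markers had a mean of 0.72 and first-segment markers a mean of 0.80 in the authors' deposited table. The leading named genes of PT-S2 were Trdn, Cyp4a12b, Kynu and Acnat2.

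PT-injury/repair held 4.56% of the listed UMIs and carried the markers of injured tubule. In it, 10 of 13 injured proximal tubule markers passed, with a mean log2 fold change of 4.03 in the authors' deposited table. Havcr1, which encodes kidney injury molecule 1, averaged 0.346 normalised UMIs per nucleus there and at most 0.00494 in the other 5 proximal tubule clusters. The adhesion molecule gene Vcam1 averaged 0.405 there and at most 0.00903 in those 5. The megalin gene Lrp2 was at 0.792 in PT-injury/repair, against 3.55 to 5.83 in the other 5 proximal tubule clusters. Its leading genes by fold included the keratin gene Krt20 and the potassium channel gene Kcnh8. Markers of types without a cluster of their own also passed there, with 8 of 10 thin limb markers (mean 3.10 in the authors' deposited table) and 4 of 7 parietal epithelial markers (2.48). So did 5 of 10 cycling cell markers (2.44) and 3 of 7 urothelial markers (2.30).

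Outside the proximal tubule, marker lists were highest in the clusters that bear their names. All 10 podocyte markers passed in Podocyte, where Ptpro was among the 5 leading genes. The sodium-chloride cotransporter gene Slc12a3 was among the 5 leading genes of DCT+CNT, with an average of 33.7 normalised UMIs per nucleus. Principal cell markers passed for 10 of 10 genes in PC, intercalated cell type A markers for 10 of 10 in IC-A/IC-B, and endothelial markers for 12 of 12 in both EC1 and EC2. Thick ascending limb markers passed for 9 of 10 genes in TAL, connecting tubule markers for 7 of 9 in CNT, and macrophage and dendritic cell markers for 14 of 14 in Immune cells. Mixed-1, which the authors did not name for a type, had fibroblast and mesangium markers as its highest list, with 11 of 14 past the threshold. In mixed-2 no list had 3 markers past it, and its leading genes included Cd248, Ednra and Hgf.

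**Figure D1:**
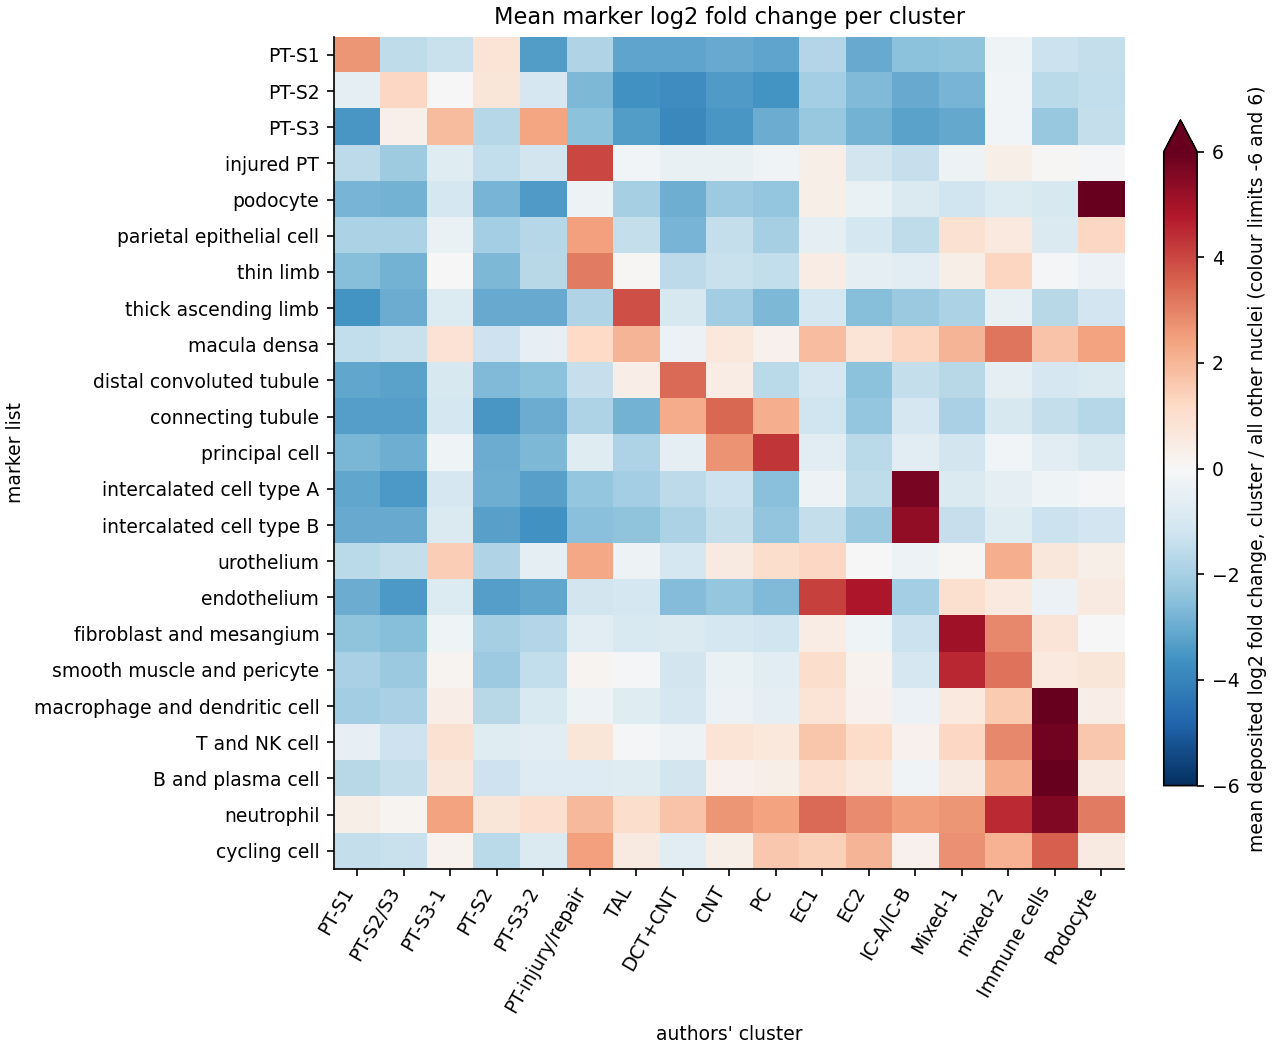
Mean deposited log2 fold change of each marker list (vertical axis) in each of the authors' 17 clusters (horizontal axis) against all other nuclei, with colour from blue (lower) to red (higher). The PT-injury/repair column is highest for injured proximal tubule markers, at 4.03, and the Podocyte column for podocyte markers, at 6.16.

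The comparison of Cis9w with CT9w asks what differs in proximal tubule nuclei weeks after the last of the repeated doses. Injury and failed-repair genes were higher in the Cis9w pool, and 6 of 10 marker genes of the third tubule segment were lower. Havcr1 rose 53-fold (interval 14.5 to 441), from 2 UMIs in CT9w to 177 in Cis9w. The organic anion transporter gene Slco1a1 fell 26.8-fold (interval 19.7 to 37.4), from 690 UMIs to 43. Of 21312 measured genes, 212 were higher and 242 lower at a p under 0.05 in the authors' deposited table. At or above the expression floor, 161 were higher and 190 lower. The test behind these p-values is not given in the sources used here, so they are not read as a comparison of animals, and a gene described as having risen or fallen passed that test only. At a p under 0.01 the count dropped to 269 genes, 114 higher and 155 lower.

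**Figure D2:**
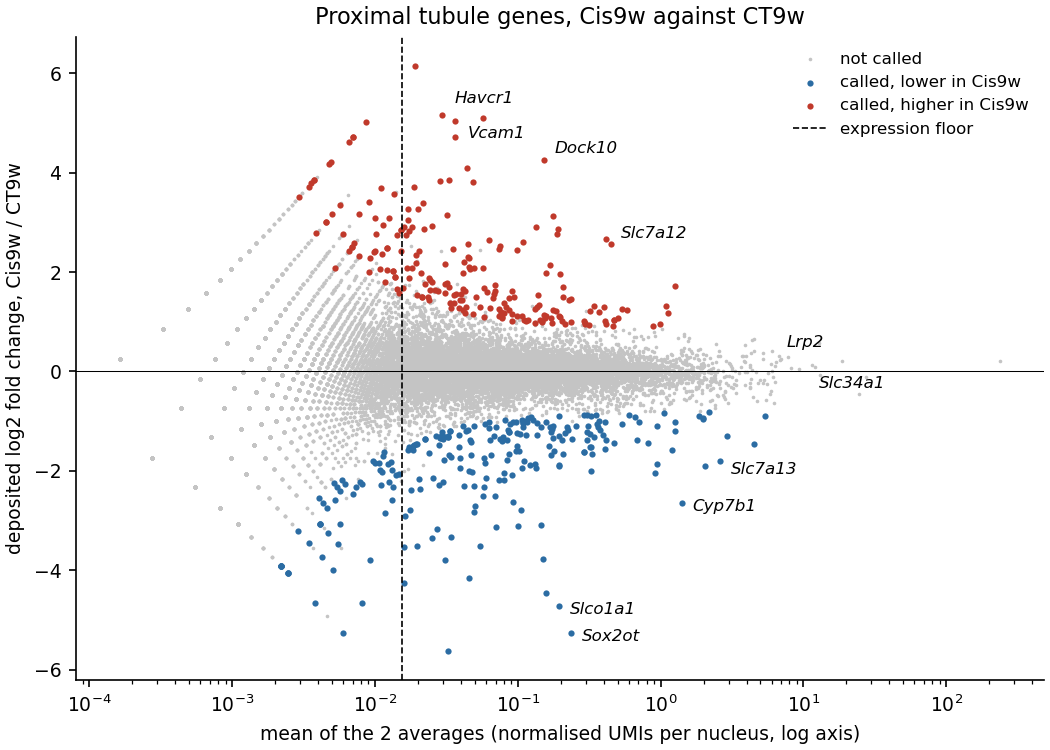
Each point is a gene in proximal tubule nuclei, with the mean of the CT9w and Cis9w averages on the horizontal log axis and the deposited log2 fold change of Cis9w over CT9w on the vertical axis. Red points are the 212 genes called higher, blue points the 242 called lower, grey points the rest, and the dashed line is the expression floor of 0.0154 normalised UMIs per nucleus.

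Among the 12 largest rises at the floor, most genes had their highest proximal tubule average in PT-injury/repair. Vcam1 rose 43.3-fold (14.6 to 212), from 3 UMIs to 217. Kcnh8 rose 41.1-fold (17.4 to 127). Dock10, a guanine nucleotide exchange factor gene, rose 19.9-fold (13.6 to 30.3), from 27 UMIs to 896. Sorcs1 rose 19.2-fold, Ntm 16.3-fold and Eda2r, a p53 target that encodes a receptor for ectodysplasin A2, 16.2-fold. Trp53cor1, a long noncoding RNA gene induced by p53, rose 16.5-fold (7.41 to 45.5), and it lies near Cdkn1a on chromosome 17. The largest log2 fold change belonged to Gm17268, which overlaps the chemokine gene Ccl2 on the opposite strand. Gm17268 had 0 UMIs in CT9w and 117 in Cis9w, a ratio of 23.4 when CT9w is set to 3 UMIs over the group. The lower end of its counting interval was 18.7. Cyp27b1, which encodes the enzyme that makes active vitamin D, rose 12.2-fold (5.43 to 33.8) and was highest in PT-S1. Ugt1a10 rose 15.3-fold, but this gene shares its span on chromosome 1 with other Ugt1a genes, so its UMIs cannot be assigned to it with certainty. Havcr1 lies at 46735080 to 46779578 on chromosome 11 and Vcam1 at 116109949 to 116129688 on chromosome 3 of mm10.

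The 12 largest falls included genes of different functions. Sox2ot, a long noncoding RNA gene, fell 39.3-fold (28.2 to 56.5), from 847 UMIs to 36, and Gm38505, which lies on the opposite strand within Sox2ot, fell 65.1-fold (21.7 to 320.4). Both lie on chromosome 3, where Sox2ot spans 34104270 to 34682619. Slco1a1 spans 141907282 to 141946962 on chromosome 6. Anks1b fell 22.4-fold (16.3 to 31.6), the potassium channel gene Kcnk2 23.4-fold (8.64 to 88.8), the collagen gene Col19a1 19.0-fold (11.0 to 35.5) and the sodium leak channel gene Nalcn 14.9-fold. Gm15441, antisense to Txnip, fell 13.9-fold. Shoc1, Hmcn1, Pzp and Col6a6 fell between 10.8-fold and 12.9-fold.

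**Figure D3:**
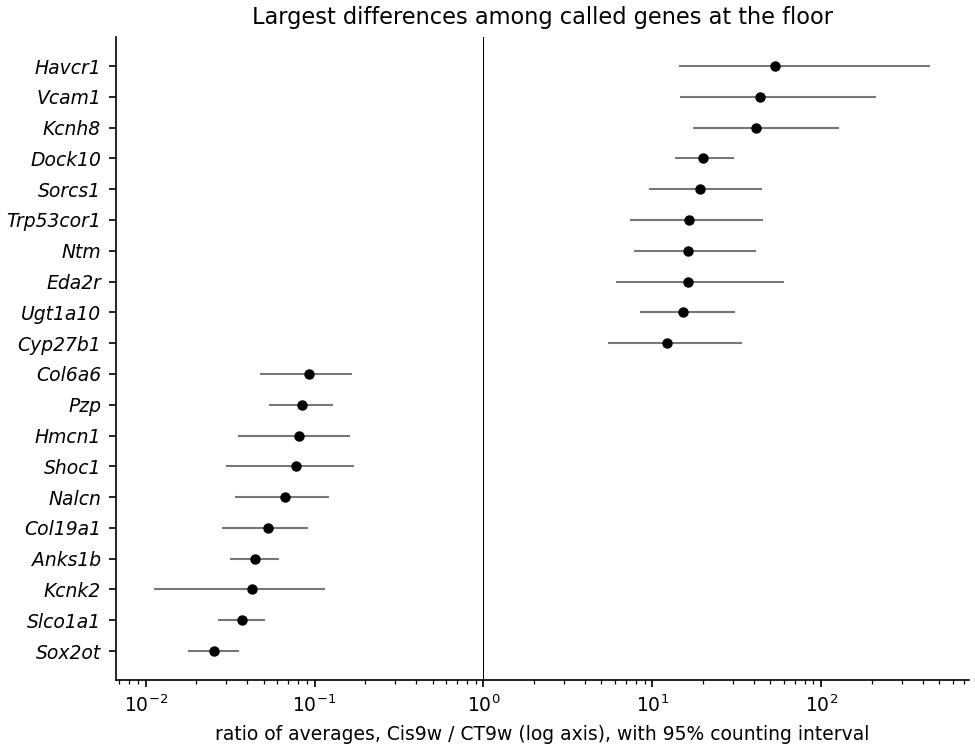
Ratio of the Cis9w to the CT9w average (horizontal log axis) for genes among the largest rises and falls in proximal tubule nuclei, with the 95% counting interval of each as a bar. Gene models without a name are left out, and the ratios run from 53 for Havcr1 down to 0.0254 for Sox2ot.

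Tubular injury and failed-repair genes had the highest median among the 24 pathway and quality lists at the floor, and were second to endoplasmic reticulum stress (0.62 against 0.96) with a floor at the 75th percentile. Of its 37 members at the floor, 19 rose, 1 fell and 17 did not pass. Their median log2 fold change in the authors' deposited table was 0.98, against -0.08 to 0.13 for the middle 95% of 10000 random lists matched on level. Beside Havcr1, Vcam1 and Dock10, the potassium channel interacting protein gene Kcnip4 rose 7.33-fold (5.87 to 9.27) and the cadherin gene Cdh6 6.90-fold (5.54 to 8.68). Spp1, which encodes osteopontin, rose 2.75-fold (2.38 to 3.18), from 232 UMIs to 1066. The member that fell was Bcat1, a branched-chain amino acid aminotransferase gene, by 6.25-fold (4.86 to 8.13). Lcn2, the gene of the injury marker NGAL, had 0 UMIs in CT9w and 7 in Cis9w, with a p of 0.746 in the authors' deposited table, so no difference was detectable at this depth. Injured proximal tubule markers, all of which are shared with other lists, had 8 rises among 9 members at the floor and a median of 1.46. Some marker lists of other kidney cell types were higher in the same comparison, with medians up to 1.37 for parietal epithelial cells among lists placed against random lists. Thin limb markers were lower, with a median of -0.68 over 4 members at the floor, none of which passed. Thick ascending limb and distal convoluted tubule markers lay inside their random ranges.

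Genes of p53 signalling, inflammation and complement were higher in part. In the list of p53 targets, 3 of 29 members at the floor rose and none fell, and the median of 0.42 in the authors' deposited table lay above the random range of -0.09 to 0.16. With a floor at the 75th percentile it was 0.20, still above its range. Plk3 rose 3.26-fold and Btg2 3.41-fold. Cdkn1a, the gene of the cell cycle inhibitor p21, was below the floor, with 3 UMIs in CT9w and 78 in Cis9w, a ratio of 15.6 (5.13 to 77.1) and a p of 1.44e-05 in the authors' deposited table. In the inflammatory and NF-kB list, 5 of 21 members rose, among them Relb 5.50-fold (2.95 to 11.4), Bcl3 3.56-fold and Birc3 3.07-fold. Another was Vcam1, which is also on the injury list. Tnfsf10, which encodes the death ligand TRAIL, fell 3.43-fold (2.74 to 4.31). The list's median was 0.60, above the random range of -0.12 to 0.20. The complement genes C3 and Clu rose 8.68-fold (3.83 to 24.3) and 2.64-fold, while the median of the 8 complement members was -0.09 and their mean 0.34. Both genes are also among the injury list members that rose. Interferon and antigen presentation genes had 17 members at the floor, none of which passed, and a median of 0.06.

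Of 17 endoplasmic reticulum stress genes at the floor, 6 rose, none fell and 11 did not pass, with a median of 0.88 in the authors' deposited table against a random range of -0.12 to 0.18, and 0.58 without a floor. Hspa5, the gene of the chaperone BiP, rose 2.05-fold (1.73 to 2.45), and the disulfide isomerase genes Pdia4 and Pdia6 rose 2.36-fold and 2.03-fold. Each of these 3 had its highest proximal tubule average in PT-S1, not in PT-injury/repair. Cytoskeleton and adhesion genes had a median of 0.28, above the random range, with rises in Cdh6, Cald1 (3.10-fold) and Itga6 (1.89-fold) among 32 members. Glycolysis genes had a median of 0.23 above their random range of -0.12 to 0.20, with 1 rise, Eno1 at 2.19-fold, among 19. Regulated cell death genes had a median of 0.19 above their range of -0.13 to 0.16, with 2 rises among 19, Birc3 and Dapk2 (2.81-fold). The positions of the glycolysis and cell death lists changed under other settings.

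Markers of the third proximal tubule segment were lower in Cis9w, while those of the first were not. Of the 10 third-segment markers, 6 fell and none rose, with a median log2 fold change of -1.11 in the authors' deposited table against a random range of -0.20 to 0.15. Cyp7b1, an oxysterol hydroxylase gene, fell 6.27-fold (5.88 to 6.69), from 4453 UMIs to 1186. Slc7a13 fell 3.49-fold (3.35 to 3.63), the acyl-CoA synthetase gene Acsm3 3.99-fold and the organic anion transporter gene Slc22a7 4.75-fold. Cyp7b1, Slc7a13, Acsm3 and Slc22a30 are also on the list of male-biased genes in the closing section, so the falls of these lists share genes. The second-segment marker Cyp2e1 is on that list too. The 8 first-segment markers had a median of 0.11, inside the random range, and none passed. Among 8 second-segment markers 2 fell, Cyp2e1 2.59-fold and Fmo5 2.85-fold, and the list's median was 0.01 with a mean of -0.23. Mitochondrially encoded transcripts were lower in the same comparison, with a list median of -0.56.

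Most transport genes of the proximal tubule did not differ by the deposited test. Of 48 solute transporter and endocytic receptor genes, 1 rose, 5 fell and 42 did not pass, and the median of -0.11 in the authors' deposited table lay below the random range of -0.08 to 0.07. The ratio of the Cis9w to the CT9w average was 1.18 (1.15 to 1.20) for Lrp2 and 1.09 (1.07 to 1.11) for the phosphate transporter gene Slc34a1. It was 1.03 (0.944 to 1.12) for Slc5a2 and 1.14 (1.03 to 1.25) for the organic anion transporter gene Slc22a6. These 4 genes had p-values of 1 in the authors' deposited table. The rise was Slc7a12, an amino acid transporter gene that was highest in PT-S3-2, at 5.93-fold (5.18 to 6.80). Slc7a12 is also a female-biased gene, and Slco1a1, Slc7a13 and Slc22a30, among the falls, are male-biased genes of the closing section. Among 14 proximal tubule transcription factor genes none passed, and their median was -0.12, inside the random range. Cisplatin transport and metabolism genes had a median of -0.17, just below their random range of -0.14 to 0.17, although 2 of 15 rose, the efflux pump gene Abcc4 2.25-fold and the glutathione transferase gene Gsta2 2.5-fold. That list fell inside the random range under 3 of 5 other settings.

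Fatty acid oxidation and peroxisome genes moved both ways. Of 50 members at the floor, 5 fell and 2 rose, with a median of -0.12 in the authors' deposited table against a random range of -0.06 to 0.10. Cyp4b1 fell 2.73-fold (2.66 to 2.82), from 12016 UMIs to 7338, and Cyp4a32 fell 3.84-fold. Cyp4a14 rose 5.85-fold (4.22 to 8.32) and the hydroxyacid oxidase gene Hao2 2.30-fold. Cyp4b1 and Acsm3, which fell, are also male-biased genes of the closing section, and Cyp4a14 is a female-biased one, so these results share genes. Cyp4a14 and Cyp4a32 both lie on chromosome 4, and whether UMIs are split between related Cyp4a genes was not tested. In amino acid metabolism and gluconeogenesis, Kynu rose 2.39-fold and Gldc 2.36-fold, and the other 33 members at the floor did not pass, with a list median of 0.06. None of the 39 nuclear-encoded respiratory chain genes passed, and their median of -0.05 lay inside the random range.

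A further 5 lists lay inside the range of matched random lists at the floor. Profibrotic and matrix genes had a median of 0.12, with a rise in Col18a1 (2.46-fold) and a fall in Lamb3 (2.14-fold) among 27. Senescence genes had a median of 0.06 and 1 rise, Serpine2 at 4.72-fold (3.16 to 7.34). Cell cycle genes had a median of 0.19, and Cenpe, the only member at the floor that passed, fell 3.02-fold from 47 UMIs to 26. Autophagy and lysosome genes had a median of -0.02 with none past the test. Oxidative stress, iron and NRF2 genes had a median of -0.04, a rise in Acsl4 (2.07-fold) and a fall in Sod1 (1.96-fold). Without the floor, the profibrotic (0.30), senescence (0.29) and cell cycle (0.35) medians lay above their random ranges.

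**Figure D4:**
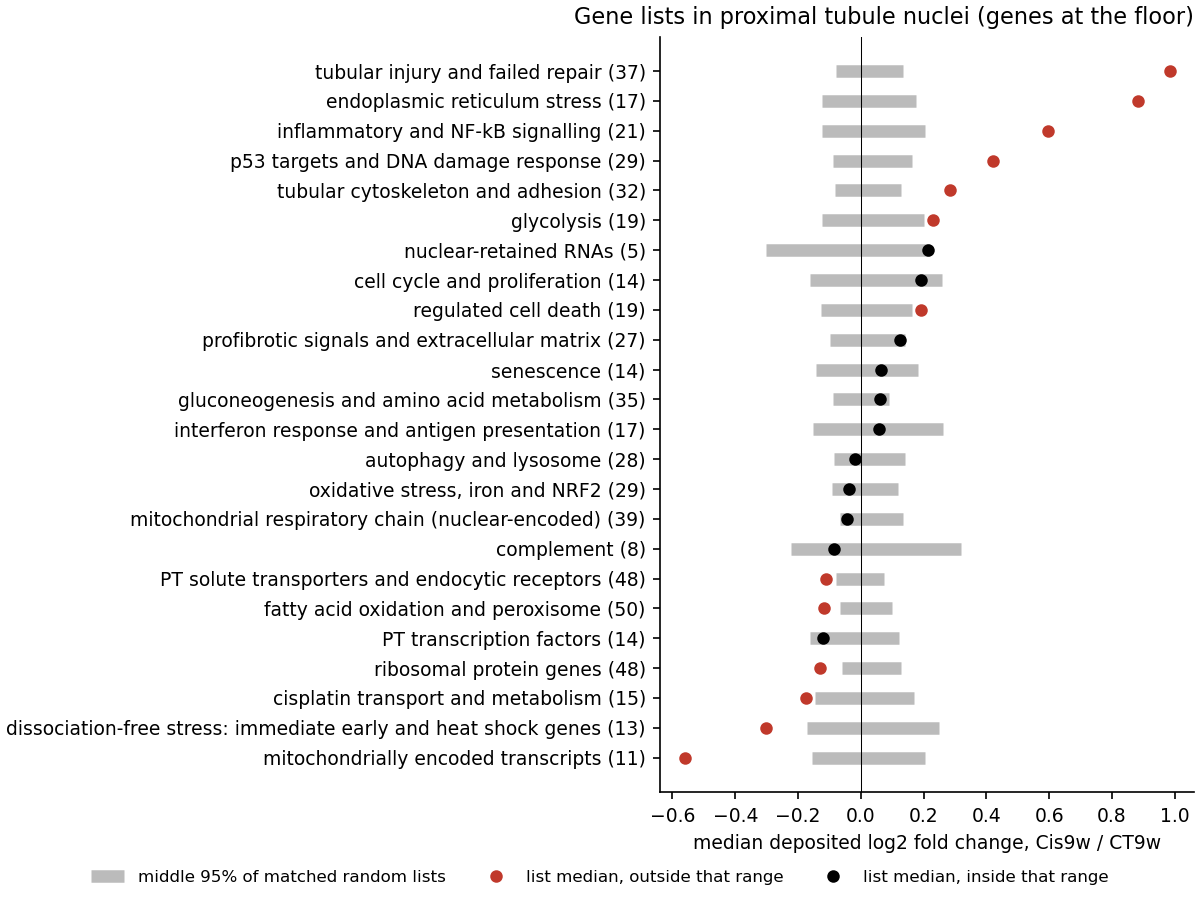
Median deposited log2 fold change of each gene list in proximal tubule nuclei (points; number of members at the floor in brackets) beside the middle 95% of 10000 random lists matched on level (grey bars). The 13 red points lie outside their bars, from 0.98 for tubular injury and failed repair to -0.56 for mitochondrially encoded transcripts.

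Lists that reflect RNA quality or free RNA also moved with the group, beside the falls described above. Mitochondrially encoded transcripts had a median of -0.56 over 11 members in the authors' deposited table, and mt-Nd3 fell 2.42-fold. Ribosomal protein genes had a median of -0.13, with none of 48 past the test, and immediate early and heat shock genes had a median of -0.30. In that list Egr1 fell 5.72-fold (4.18 to 7.95) and Klf6 rose 2.66-fold. All 3 lay below their random ranges at the floor, while nuclear-retained RNAs, with a median of 0.21, lay inside theirs. The immediate early and heat shock list lay inside its range without a floor (-0.14) and with a floor at the 75th percentile, where the nuclear-retained RNAs lay above theirs.

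Markers of other kidney cell types moved as well. The 7 lists above their random range were podocyte, parietal epithelial cell, connecting tubule, principal cell, both intercalated cell types and endothelium. Connecting tubule markers had a median of 0.58 in the authors' deposited table, and their summed average was 1.12 normalised UMIs per nucleus in CT9w and 1.89 in Cis9w. Endothelial markers had a median of 0.70, with summed averages of 0.226 and 0.363 and none of 8 past the test. Parietal epithelial markers had a median of 1.37 over 4 members, in which Akap12 (3.11-fold) is also an injury list member. Principal cell markers had a median of 0.84 over 4 members, where Scnn1b rose 3.25-fold and Hsd11b2 3.03-fold. Intercalated type A had a median of 0.95 over 3 members, none of which passed, and type B one of 1.20 over 4. Summed averages in CT9w and Cis9w were 0.0628 and 0.0977 for principal cells, 0.0442 and 0.0840 for type A, 0.191 and 0.191 for type B, 1.31 and 1.54 for parietal epithelial cells, and 4.22 and 4.35 for podocytes. Without a floor the type A median was 0.55, inside its random range. Slc4a9 rose 3.34-fold and Dnase1 fell 2.41-fold among the type B markers. Podocyte markers had a median of 0.48, with a rise in Thsd7a (5.56-fold). Thick ascending limb markers had a median of -0.16 and a mean of 0.11, with a rise in Erbb4 (3.29-fold), and distal convoluted tubule markers a median of 0.06 and a mean of -0.03, both inside the random range. Thin limb markers had a median of -0.68 over 4 members, below their random range, and none of the 4 passed. Macula densa (1.5), urothelium (0.18), fibroblast and mesangium (0.40), smooth muscle and pericyte (-1.13) and cycling cell (-1.57) lists each had 1 member at the floor. Macrophage and dendritic cell (-0.52) and T and NK cell (0.13) lists had 2 members each, and the B and plasma cell and neutrophil lists had 0.

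The last comparison sets the proximal tubule difference beside the profile of each cluster. Genes higher in Cis9w tended to be those of PT-injury/repair, and genes lower in Cis9w more often had their highest proximal tubule average in PT-S3-2 or PT-S2/S3. Across 10656 genes at the floor, Pearson's r between the log2 fold change of Cis9w over CT9w and that of PT-injury/repair over all other nuclei was 0.414 (Spearman's rho 0.339), both from the authors' deposited tables. The r was -0.475 for PT-S3-1, -0.357 for PT-S3-2, -0.320 for PT-S2/S3, -0.0982 for PT-S2 and 0.0290 for PT-S1, and it ran from -0.00602 to 0.212 for the other 11 clusters. PT-S3-1 also carried transcripts typical of free RNA, described in the closing section. When the UMIs of each gene were split between the pools at random, r lay between -0.0392 and 0.0362 for all 17 clusters in 200 draws, a range that holds counting noise only and leaves out differences between nuclei and animals. With a floor at the 75th percentile the r was 0.240 for PT-S1 and 0.0899 for PT-S2. Genes are not independent replicates, so no p-value is given, and the cluster profiles include proximal tubule nuclei of both groups, so the fold changes compared can share nuclei. Of the 161 genes called higher at the floor, 107 (66.5%) had their highest proximal tubule average in PT-injury/repair, against 35.8% of all 10656 genes. Of the 190 called lower, 88 (46.3%) were highest in PT-S3-2 and 36 (18.9%) in PT-S2/S3, against 16.1% and 7.37% of all genes, while PT-S3-1 had 42 (22.1%) against 21.4%.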

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

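The tests of a female animal, of other cell types, of less free RNA, of free RNA against equally enriched genes, and of the mix with other weights or without the injury genes were chosen only after the results were seen, and the fitted mix had been seen before the bounds of the tests that use it were written. Intervals of medians, mix shares and r from here on come from resampling genes. They treat genes as independent and leave out differences between nuclei and animals.

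The cluster table carries a signal from nuclei that none of its 17 columns lists. Solving the deposited fold changes for all other nuclei gave 7613346 UMIs outside the listed clusters, 17.4% of the summed size factors of all nuclei. Kap, an androgen-regulated gene expressed strongly in mouse proximal tubule, had 29708 UMIs there, or 7.84 normalised UMIs per nucleus against 1.64 in the listed clusters pooled, with 8.03 in PT-S3-1 and 6.61 in mixed-2. The tables also differ in what they count, since 114 genes of the proximal tubule table have no row in the cluster table and hold 119 UMIs, at most 3 per gene.

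Genes that are male-biased in mouse proximal tubule were lower in Cis9w: of 13 such genes, listed after their values were seen, 9 fell, with a median log2 fold change of -1.45 in the authors' deposited table. Cyp7b1, Slc7a13, Slc22a30 and Acsm3, which fell, are also third-segment markers, so this result and the fall of that marker list share genes. The other genes that fell were Slco1a1, Kap, Cyp4a12a, Cyp2e1 and Cyp4b1. Genes are therefore also shared with the transporter, second-segment and fatty acid lists. A female animal is argued against by 4 Y-linked genes with a median of -0.0609 (-0.12 to 0.46) and by 2 Xist UMIs in each group. Free RNA stays undecided: the median enrichment in the unlisted nuclei, 0.53 (0.41 to 1.00), met neither bound, and the median difference from equally enriched genes, -1.36 (-1.78 to -0.57), excludes nothing because the genes were listed with their falls in view and the unlisted nuclei only stand in for free RNA. A different mix of the authors' clusters fell short by a median of 0.95 (0.59 to 1.24), and by 0.81 and 0.86 with other weights. This shortfall excludes nothing either, because the genes were listed with their falls in view. A different mix as the whole cause stays undecided. A lower androgen response after cisplatin is a hypothesis that was not tested, and a difference between the animals of the 2 groups also stays open.

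Injury genes higher in Cis9w may come from a share of injury/repair nuclei, since the fitted mix gave PT-injury/repair 9.97% of Cis9w (9.30% to 10.6%) and 0.110% of CT9w (0 to 0.446%). The mix predicted a median log2 fold change of 2.13 (0.81 to 2.67) for the 19 injury genes that rose, where 1.98 was observed, but the interval crosses the bound of 1 set for it, so this stays open. Fitted without the 47 genes of the list, the mix predicted 2.04 (0.78 to 2.53) for these 19 and 0.57 (0.39 to 1.47) for all 37 at the floor, where 0.98 was observed, and -0.14 for the 37 without the injury/repair part. Clusters outside the proximal tubule took 1.39% of the Cis9w mix (1.23% to 1.60%) and 0.432% of CT9w (0.140% to 0.876%). CNT took 0.727% (0.449% to 0.819%) and IC-A/IC-B 0.249% (0.201% to 0.285%) of Cis9w, and each took 0 of CT9w. These shares were small, but they were known when the bound of this test was written, so they exclude nothing. Nuclei of types with a cluster of their own stay undecided. So do parietal epithelial nuclei, whose markers pass in PT-injury/repair. Thin limb markers, which pass there too, were lower in Cis9w, with a median of -0.68 over 4 members at the floor. None of the 4 passed the deposited test, and the median over all 10 without a floor was -0.56. The cluster profiles pool both groups, so more nuclei in this state and a stronger state in as many nuclei also stay open.

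Mitochondrial, globin and other transcripts typical of free RNA were lower in Cis9w. Of the 100 genes most enriched in the unlisted nuclei, 78 reached the floor, and their median log2 fold change was -0.44 (-0.56 to -0.37), below -0.04, the lower end of matched random lists. Only 6 of the 78 passed the deposited test, all lower, and of 4 globin genes, all lower, only Hbb-bs did. Less free RNA in the Cis9w pool may account for this but stays undecided, since the fitted mix took 0 of the unlisted profile in CT9w and 0 in Cis9w (0.155% with equal weights). A share of PT-S3-1 nuclei in CT9w only, 7.31% of the mix (2.68% to 11.1%) and 0 with equal weights, stays undecided, since the predicted median for these genes was -0.31 with PT-S3-1 and -0.04 without it, but -0.04 either way with equal weights. PT-S3-1 itself carried such transcripts, with averages of 0.182 for Hbb-bs and 0.551 for mt-Co2. The other proximal tubule clusters had at most 0.0322 and 0.163. The fit therefore cannot tell a share of this cluster from free RNA.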

How the results depend on the processing

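The count without enriched genes, and the mix with other weights or without the injury genes, were chosen only after the results were seen. No paired analysis was possible because both tables pool nuclei and no column is labelled with a sample, so replicate numbers could not be used as a block and leaving out a replicate was not run. Depth limits genes near 3 UMIs, such as Lcn2 and Cdkn1a. Of 95 pathway and quality list values (medians or means) under other settings 83 kept their place relative to the random range, and 13 of 14 for marker lists, leaving out centring on the median, which cannot move a list. Some of the settings counted could hardly move a list either. Recomputing from the averages barely changes a value, and lists wholly at the floor keep their median without it. Recomputing from the averages or centring turned no sign among the 80 named genes, but neither could move them far. The 454 called genes became 269 at a p under 0.01, by construction, with 114 higher and 155 lower. They became 425 without genes at least 2-fold enriched in the unlisted nuclei, with 211 higher and 214 lower. The cisplatin transport and metabolism median moved inside the random range without a floor (-0.0872), with a floor at the 75th percentile (-0.0839) and as a mean (-0.0527). Glycolysis did so at the 75th percentile (0.15) and as a mean (0.21), and regulated cell death at the 75th percentile (0.16). The immediate early and heat shock list did so without a floor and at the 75th percentile (both -0.14), and intercalated cell type A without a floor (0.55). The profibrotic (0.30), senescence (0.29) and cell cycle (0.35) medians moved above the range without a floor, and nuclear-retained RNAs (0.21) at the 75th percentile. For these 9 lists the cause was not tested. At the 75th percentile the injury median was 0.62, that of p53 targets 0.20 and that of fatty acid oxidation -0.21, each still outside its range. As a mean at the median floor, solute transporters were at -0.22 and regulated cell death at 0.35, also outside. Without a floor, regulated cell death (0.32), injured proximal tubule markers (2.77) and podocyte markers (0.84) had higher medians, above their ranges. Counted by markers among each cluster's top 50 genes, 6 clusters in place of 14 had their own list highest, because most lists had no gene there. The r of the proximal tubule difference with PT-injury/repair was 0.451 at the 75th percentile floor, 0.339 by Spearman and 0.678 over genes with p under 0.05, always positive. The r with PT-S2 reversed from -0.0982 to 0.0899 at the 75th percentile floor, and that with PT-S1 moved from 0.0290 to 0.240 there and to 0.129 over genes with p under 0.05, and the cause was not tested. The share of PT-injury/repair in the Cis9w mix was 9.04% with inverse-level weights and 14.2% with equal weights, and in CT9w 0.936% and 0. Fitted without the injury genes it was 9.81% and 0.267%. The share of PT-S3-1 in CT9w was 8.18% with inverse-level weights and 0 with equal weights.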

Other observations

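The female-biased genes described here, and the reading of the fitted mix below, were chosen only after the results were seen. Female-biased genes of mouse proximal tubule were higher in Cis9w in part. Prlr, the prolactin receptor gene, had 206 UMIs in CT9w and 2181 in Cis9w, a 6.34-fold rise (5.49 to 7.35). The efflux pump gene Abcc3 had 4 and 63 UMIs, a ratio of 9.43 (3.51 to 35.7), below the floor. Both Prlr and Slc7a12 were highest in PT-S3-2, the cluster whose markers Cyp7b1, Slc7a13 and Acsm3 were lower in Cis9w, so genes highest in that cluster moved in both directions. Slc7a12, Prlr and Cyp4a14 had a median log2 fold change of 2.56 in the authors' deposited table, where the fitted mix of clusters gave -0.30. Akr1c18, another female-biased gene, had 5 UMIs in CT9w and 0 in Cis9w and did not pass.

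PT-S2 and PT-S2/S3 may separate the groups. The mix of CT9w took 54.2% from PT-S2/S3 and 0 from PT-S2, whereas that of Cis9w took 13.1% and 45.5%. With inverse-level and equal weights, PT-S2/S3 took 49.6% and 55.5% of CT9w and 9.58% and 8.13% of Cis9w, and PT-S2 took 2.65% and 0 of CT9w and 50% and 48.2% of Cis9w. Slco1a1 averaged 0.272 normalised UMIs per nucleus in PT-S2/S3 and 0.00986 in PT-S2. The hypothesis that these clusters hold mostly nuclei of different groups was tested with the log2 ratio of PT-S2 to PT-S2/S3, which had an r of 0.340 (0.295 to 0.376) with the Cis9w over CT9w difference across genes. This was the 4th largest in size among 15 pairs of proximal tubule clusters and met neither bound written for it, so the 2 readings cannot be told apart without the group of each nucleus, which was not used here.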
